A study of Homo sapiens with 6 samples.

How the data were processed

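RNA was measured by sequencing in 6 libraries of the U937 line, 3 from lines with control plasmids and 3 from clones depleted of CTSG, ELANE and PRTN3 together, after transduction and selection with geneticin; total RNA was extracted. The authors deposited 1 table of raw counts per Ensembl gene, whole numbers without normalization. Per the submitters' processing notes, FastQC, HISAT2 2.0.0, SAMtools 1.5.9 and HTSeq 0.11.1 were used with the GRCh38.p12 build; the annotation release, the strand setting and any filter are not given in the sources used here. Every gene in the table had at least 10 counts over the 6 libraries, so genes below that were not analysed here. Symbols, positions and gene types came from GENCODE v29 by Ensembl identifier, with a match for 18771 of 18798 genes.

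Groups and replicate numbers came from the sample labels, which call the Control samples separate lines and the ΔNSPs samples independent clones. The labels give no sequencing batch or date. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom between libraries of a group was 7.65 at the lowest. Library totals ran from 11476619 to 13782854 counts, and a floor of 3 counts lies at 0.218 to 0.261 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules.

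The main test was edgeR 4.0.16 (R 4.3.3) with TMM normalization, the filterByExpr filter by group, quasi-likelihood fits without the robust option, and Benjamini-Hochberg adjustment over the 14797 genes that passed the filter, two-sided, at an adjusted p under 0.05. CPM values are counts divided by the TMM-scaled library total, on the usual scale, and errors are SD over 3 libraries. A log2 fold change is ΔNSPs minus Control, with its SE derived from the fold change and the test statistic. DESeq2 1.42.0 (Wald test) and limma 3.58.1 (voom with sample quality weights) were run as alternatives. The 31 gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. Within-group spread was the root mean square log2 CPM difference between libraries of a group, with a prior count of 2.

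The rule for named genes took the 3 targets and AZU1, CFD, MPO, GZMB and GZMH; up to 10 genes each way past the edgeR threshold, with a mean of at least 2 CPM and no overlap between the groups; up to 4 members past the threshold per list; and otherwise the member of a list with the highest mean CPM. Some genes that this rule names are not reported here. That rule gave 3 genes by change. The 10 largest changes each way among protein-coding genes past DESeq2's threshold were therefore added after the data were seen. These also had to have a mean of at least 2 CPM and no overlap between the groups.

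The tests were tested on simulated data with the spread of these libraries and 100 changed genes of each size. With a spread shared by the groups, edgeR recovered 63% of 2-fold and 97% of 4-fold changes, with 6.43% of its calls false. DESeq2 recovered 75% and 100% with 15.5% false calls, and limma voom 61% and 97% with 5.95%. With each group at its own spread, false calls were 7.65% for edgeR, 20.7% for DESeq2 and 10.2% for limma voom. Each spread was simulated a single time. Genes were drawn independently, without chromosome shifts or a background shared by some libraries, so these rates may not hold for the real libraries.

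Alternatives were other size factors, other filters, DESeq2, limma voom, the replicate number as a block, thinning to the smallest total, a test against a 1.5-fold change, and leaving out each library. Chosen after the data were seen were robust dispersions, voom without weights, leaving out shifted chromosome regions, and a covariate for a background shared by some libraries. Chromosome windows of 20 Mb used genes with a mean of at least 8 CPM, at least 20 genes a window, and a pseudocount of 0.5 CPM. A window counted as shifted beyond a median of 0.3 and beyond 1000 random gene sets of its size.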

Results

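RNA-seq read counts were obtained from 6 libraries of U937, an established human cell line of monocytic origin, after transduction with plasmids. The 3 Control libraries came from separate lines that carried control plasmids. The 3 ΔNSPs libraries came from separate clones in which CTSG, ELANE and PRTN3 had been depleted together, and the labels call these clones independent. Cathepsin G, neutrophil elastase and proteinase 3, the products of these genes, are serine proteases stored in the azurophil granules of myeloid cells. The count totals were 11866764, 13543076 and 11476619 in Control replicates 1 to 3, and 13782854, 13301870 and 12184903 in ΔNSPs clones 1 to 3. At these depths a floor of 3 counts corresponds to 0.218 to 0.261 CPM (counts scaled to a common library total). The table held 18798 genes, of which 14797 had enough counts to be tested.

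The first comparison asked whether the targeted genes were low in each clone. CTSG (ENSG00000100448) fell to 4.08% of its Control level, from 2376 ± 436 CPM to 97.1 ± 46.9 CPM (mean ± SD, n = 3 per group), a log2 fold change of -4.61 (SE 0.40; edgeR adjusted p = 0.0215). ELANE (ENSG00000197561) stood at 2.12% of its Control level, 23.9 ± 20.3 CPM against 1127 ± 179 CPM, and passed in DESeq2 (adjusted p = 4.36e-05) but not in edgeR (adjusted p = 0.145). PRTN3 (ENSG00000196415) stood at 12.8%, 39.6 ± 33.8 CPM against 310.1 ± 204 CPM, and passed in neither tool (adjusted p = 0.217 in edgeR and 0.21 in DESeq2). Every ΔNSPs library lay below every Control library for all 3 genes. Adjusted over the list alone, all 3 passed in edgeR, with adjusted p = 8.7e-06 for CTSG, 0.000254 for ELANE and 0.0208 for PRTN3.

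The clones differed in which protease transcript was lowest. PRTN3 was at 0.859 CPM (12 counts) in ΔNSPs clone 1, against 62.9 and 55.2 CPM in clones 2 and 3. ELANE was at 1.88 CPM (25 counts) in clone 2, against 42.0 CPM in clone 1 and 27.7 CPM in clone 3. CTSG read 136 CPM in clone 1, 109.9 CPM in clone 2 and 45.1 CPM in clone 3. PRTN3 also varied among the Control lines, at 539 CPM in replicate 1, 147 CPM in replicate 2 and 244 CPM in replicate 3. The edgeR call of CTSG was lost without Control replicate 2 (adjusted p = 0.232), Control replicate 3 (0.217) or ΔNSPs clone 2 (0.0932). ELANE passed without clone 1 (0.018) or clone 2 (0.00159), and PRTN3 passed without clone 1 (0.0391).

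**Figure D1:**
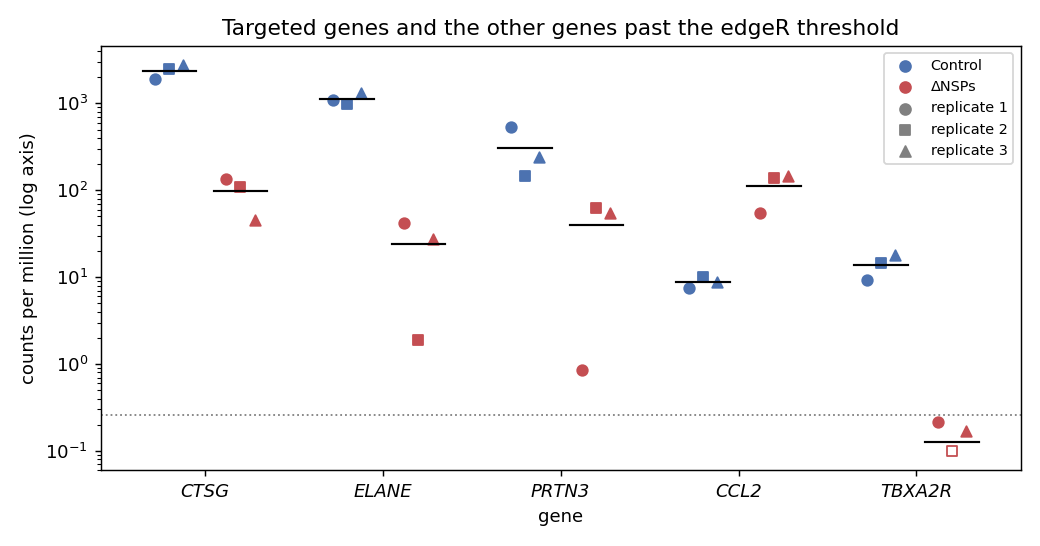
CPM of the targeted genes CTSG, ELANE and PRTN3 and of CCL2 and TBXA2R in each library, on a log axis; blue points are Control lines, red points ΔNSPs clones, the marker shape gives the replicate, and black bars are group means. The dotted line is the floor of 3 counts in the smallest library (0.261 CPM), and the open square is a library with 0 counts, drawn at the foot of the axis; every ΔNSPs clone lies below every Control line for the 3 targeted genes and TBXA2R, and above it for CCL2.

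PRTN3 (positions 840960 to 848175) and ELANE (851014 to 856247) lie side by side on chromosome 19 of GRCh38, between AZU1 and CFD, and CTSG (24573522 to 24576260) lies on chromosome 14. AZU1, which encodes azurocidin, was at 287 ± 88.7 CPM in ΔNSPs against 438 ± 82.1 CPM in Control (log2 fold change -0.61, SE 0.25; edgeR adjusted p = 0.262). CFD, complement factor D, was at 11.1 ± 9.56 CPM against 18.8 ± 3.89 CPM (edgeR adjusted p = 0.489). MPO, myeloperoxidase, was low in every library, at 1.87 ± 1.64 CPM against 0.593 ± 0.391 CPM (edgeR adjusted p = 0.319). GZMH had 0.501 CPM at most and was not tested, and GZMB was not analysed here. Among the 18 measured genes of the list beside ELANE and PRTN3, 0 passed in edgeR or DESeq2 and 0 adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05, and the median log2 fold change was 0.23 (camera adjusted p = 0.186). PTBP1, the most highly expressed of them, was at 720.3 ± 21.5 CPM against 617 ± 44.7 CPM. That list passed without Control replicate 1 (camera adjusted p = 0.0164) or without ΔNSPs clone 1 (0.0226). The whole list lies in the first window of chromosome 19. The 370 expressed genes there had median log2 ratios to the Control mean of 0.029, 0.26 and 0.46 in clones 1, 2 and 3. The list's mean log2 CPM, relative to the mean of all libraries, was -0.32, 0.22 and 0.31 in those clones. An effect beside the targeted genes therefore cannot be told from a shift of the whole window.

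Over all genes, TBXA2R and CTSG fell and CCL2 rose in ΔNSPs. TBXA2R (ENSG00000006638), the thromboxane A2 receptor gene on chromosome 19 (3594506 to 3606840), went from 13.9 ± 4.40 CPM to 0.128 ± 0.113 CPM, with 3, 0 and 2 counts in the clones (log2 fold change -6.66, SE 0.57; edgeR adjusted p = 0.0215). CCL2 (ENSG00000108691) on chromosome 17 (34255218 to 34257203), which encodes a chemokine that attracts monocytes, went from 8.84 ± 1.26 CPM to 113 ± 50.2 CPM, a 12.8-fold increase (log2 fold change 3.68, SE 0.37; edgeR adjusted p = 0.0443). These were the 3 genes that changed at an adjusted p under 0.05 in edgeR, 1 higher and 2 lower, and all 3 changed at least 2-fold. The gene ranked next had an adjusted p of 0.0773. At an unadjusted p under 0.05 there were 2638 genes. In 23.7% of the tested genes the groups did not overlap, against 10% if the libraries were alike apart from independent noise. Another split, Control replicate 1 with clones 2 and 3 against the rest, gave 2423 genes at an unadjusted p under 0.05. The 2638 genes and the 23.7% therefore do not measure the depletion alone.

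The count of changed genes depended on the tool and on single libraries. DESeq2 called 515 genes, 247 higher and 268 lower, 139 of them at least 2-fold, and limma voom with sample quality weights called 2. Without ΔNSPs clone 1, edgeR called 928 genes, 457 higher and 471 lower, among them CTSG, TBXA2R and CCL2. Without Control replicate 1 it called 20, without clone 2 it called 2, and without clone 3 it called 1. Without Control replicate 2 or 3 it called 0, with 1408 and 1413 genes at an unadjusted p under 0.05; DESeq2 and limma were run on all 6 libraries alone. CCL2 lost its call without Control replicate 1 (adjusted p = 0.0621), 2 (0.527) or 3 (0.532) and without clone 2 (0.0932) or 3 (0.117). TBXA2R lost its call without Control replicate 2 (0.232) or 3 (0.217) and without clone 3 (0.117).

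Since the fixed rule named so few genes, protein-coding genes with the largest changes among DESeq2's calls are given as well. This choice was made after the data were seen. They were picked among calls with a mean of at least 2 CPM and no overlap between the groups. Of the 515 DESeq2 calls, 476 had no such overlap. That the genes below were higher in all 3 clones than in every Control line is thus a result of the choice. None of them passed the edgeR threshold, and no shared function was tested among them. CXCL8, which encodes interleukin 8, was at 9.82 ± 2.72 CPM in ΔNSPs against 2.19 ± 1.65 CPM in Control (DESeq2 adjusted p = 0.00129). S100A9, a calgranulin gene, was at 31.1 ± 28.1 CPM against 4.71 ± 0.913 CPM (DESeq2 adjusted p = 0.0262), with 8.23 CPM in clone 1 and 62.5 CPM in clone 2. GPR84, a receptor for medium-chain fatty acids, was at 24.1 ± 17.0 CPM against 3.78 ± 0.823 CPM, and IL18RAP, a subunit of the interleukin 18 receptor, at 6.26 ± 2.59 CPM against 1.47 ± 0.314 CPM. CEACAM6, ITGB7 and F2RL3 had DESeq2 log2 fold changes of 2.74, 2.55 and 2.19, with the highest level in clone 2. CEACAM6 was at 9.80 and 4.70 CPM in clones 2 and 3, and in clone 1 it was little above the highest Control line (1.36 CPM). In clones 1, 2 and 3 ITGB7 was at 1.58, 7.38 and 3.78 CPM against 0.937 CPM in the highest Control line, and F2RL3 at 3.44, 18.2 and 7.05 CPM against 3.07 CPM. Without clone 2 the edgeR log2 fold changes were 1.94 for CEACAM6, 1.86 for ITGB7, 1.32 for F2RL3 and 1.71 for S100A9. The neighbouring keratin genes KRT81 and KRT86, whose sequences are close and whose annotated spans overlap, were at 6.84 ± 4.81 and 4.37 ± 2.61 CPM against 0.114 ± 0.197 and 0.163 ± 0.0858 CPM, and their counts are uncertain for that reason.

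Among DESeq2's lower calls, picked in the same way, TBXA2R, ELANE and CTSG had the largest changes. No shared function was tested among the genes below. P4HA1, a collagen prolyl hydroxylase gene, was at 43.0 ± 1.96 CPM in ΔNSPs against 177 ± 79.5 CPM in Control (DESeq2 adjusted p = 3.66e-09). It was at 87.9 CPM in Control replicate 1 and at 203 and 240 CPM in replicates 2 and 3. ALDOC, which encodes aldolase C, was at 21.5 ± 5.99 CPM against 74.8 ± 14.8 CPM (DESeq2 adjusted p = 7.04e-11). OPTN, an autophagy receptor gene, was at 9.72 ± 4.67 CPM against 37.2 ± 18.4 CPM, and IFIH1, a sensor of double-stranded RNA, at 15.8 ± 4.31 CPM against 46.8 ± 22.2 CPM. For both, Control replicate 1 was the lowest Control line, at 16.1 CPM for OPTN and 21.9 CPM for IFIH1. LRRC75B and FAM114A1 had DESeq2 log2 fold changes of -1.92 and -1.79. TIAM1, not tested in edgeR, was at 9.71 CPM in Control replicate 1 and at 0.654 and 2.34 CPM in replicates 2 and 3, against 0.273 ± 0.164 CPM in ΔNSPs. Of the 515 DESeq2 calls, 330 were also called by edgeR without clone 1.

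A few genes had no counts in a whole group, and those named here were chosen after their values were seen. GTF2IRD1 had 0 counts in the clones and 1.43 CPM in Control, at least 18.7-fold lower against a floor of 3 counts over the group. GZMA, which encodes granzyme A, had 0 counts in the Control lines and 1.21 CPM in ΔNSPs, at least 14.9-fold higher.

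Gene lists fixed before the data were examined were compared next, with limma's camera at a preset correlation of 0.01 between genes. Of the 31 lists, 3 passed an adjusted p of 0.05, and 0 passed with an estimated correlation. As many lists or more passed in 9 of the 10 splits of the 6 libraries into 3 and 3, the real one included. Of the 552 list members tested, 1 passed in edgeR over all genes (CCL2), 125 had an unadjusted p under 0.05, and 41 passed in DESeq2; these totals stand behind each count of 0 below. Below, where a list's most highly expressed member is named, it is named by rule, and every other member without an edgeR call was chosen after its values were seen. Limma's fry called 1 list as moving on balance one way, the immediate early genes, and 9 as changing in either direction. The 9 were serine protease inhibitors, p53 targets, immediate early genes, the unfolded protein response, and specific granule and calgranulin genes. The rest were NF-kB targets, glycolysis and hypoxia, granzymes, and BCL2 family and caspase genes. Fry was not run on the other splits, so whether it would call as many lists there is not known.

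Immediate early genes, which respond to stimulation and handling, rose as a group, with a median log2 fold change of 0.39 over 15 measured genes (camera adjusted p = 0.0016; adjusted p = 0.443 with an estimated correlation). The list's mean was higher in all 3 clones than in any Control line. IER2 was at 137 ± 36.6 CPM in ΔNSPs against 66.7 ± 7.28 CPM in Control, JUNB had a log2 fold change of 0.77 (SE 0.18) and FOSL1 of 0.91 (SE 0.17), and all 3 were DESeq2 calls. In edgeR, 0 of the 15 passed over all genes, 5 were higher and 1 lower at an unadjusted p under 0.05, and 4 were higher adjusted over the list alone.

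Genes of cholesterol synthesis and uptake rose as a group, with a median log2 fold change of 0.49 over 23 measured genes, 20 of them positive (camera adjusted p = 0.00128; adjusted p = 0.83 with an estimated correlation). Control replicate 1 stood apart from the other Control lines, and the clones lay above replicates 2 and 3 but not all above replicate 1. Relative to the mean of the 6 libraries, the list's mean log2 CPM was 0.50 in Control replicate 1, -0.62 and -0.70 in replicates 2 and 3, and 0.16, 0.053 and 0.60 in clones 1 to 3. In edgeR, 0 members passed over all genes or adjusted over the list alone and 2 were higher at an unadjusted p under 0.05, and ACAT2 was the DESeq2 call (log2 fold change 0.76, SE 0.20).

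Genes of glycolysis and the hypoxia response fell as a group, with a median log2 fold change of -0.15 and a mean of -0.31 over 23 measured genes (camera adjusted p = 0.0106; adjusted p = 0.83 with an estimated correlation). GPI, ALDOC, BNIP3 and PFKFB4 were the 4 lower DESeq2 calls, with log2 fold changes of -0.69, -1.80, -1.19 and -1.23. ENO1, the most highly expressed member, was at 3917 ± 129 CPM in ΔNSPs against 4891 ± 785 CPM in Control. SLC2A1, which encodes the glucose transporter GLUT1, went the other way, with a log2 fold change of 0.53 (SE 0.16). In edgeR 0 members passed over all genes, with 2 higher and 7 lower at an unadjusted p under 0.05, while 1 was higher and 5 were lower adjusted over the list alone. The list's call was lost without Control replicate 3 (adjusted p = 0.0736) or ΔNSPs clone 1 (0.124).

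**Figure D2:**
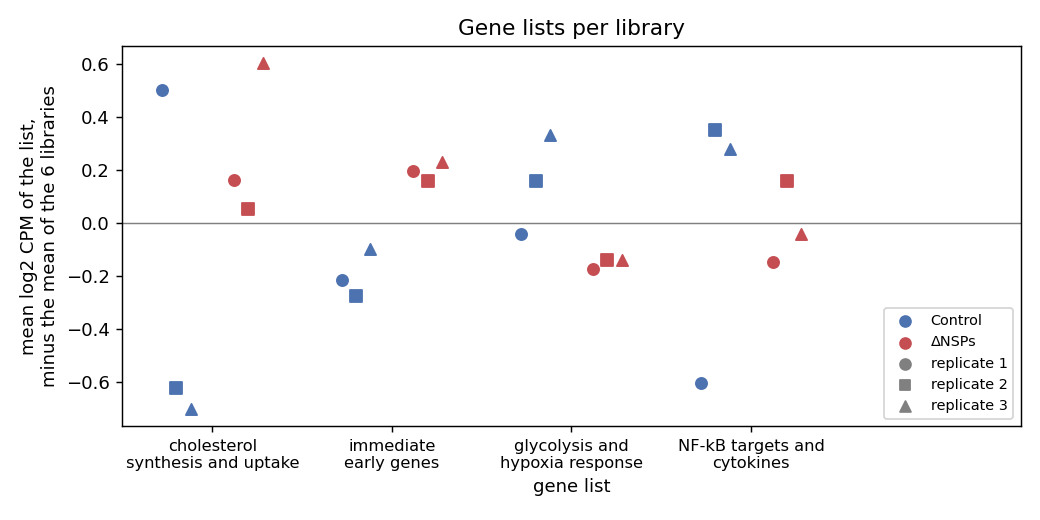
Mean log2 CPM of 4 gene lists in each library, as the difference from the mean of the 6 libraries; blue points are Control lines, red points ΔNSPs clones, and the marker shape gives the replicate. The clones lie above all Control lines for immediate early genes and below them for glycolysis and hypoxia, while Control replicate 1 lies apart from the other Control lines for cholesterol synthesis and for the NF-kB targets.

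Among inflammatory and immune genes, CCL2 was the member past the edgeR threshold over all genes. The list of NF-kB targets and cytokines had 1 higher edgeR call of 23 measured genes, CCL2, with 3 higher and 2 lower adjusted over the list alone and in DESeq2, and a median log2 fold change of -0.29 (camera adjusted p = 0.971). Its members diverged: CXCL8 and TNF had log2 fold changes of 2.14 (SE 0.51) and 1.72 (SE 0.50), while NFKB2 and BIRC3 had -1.33 (SE 0.37) and -2.21 (SE 0.78). NFKB2 was at 31.3 CPM in Control replicate 1 and at 94.2 and 92.7 CPM in replicates 2 and 3, against 32.7, 24.6 and 29.2 CPM in the clones. Without Control replicate 1 the list fell (camera adjusted p = 8.25e-05). The type I interferon list had a median of -0.13 over 27 genes (camera adjusted p = 0.581), 0 edgeR calls and 1 gene each way adjusted over the list alone.

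MHC class I genes had a median log2 fold change of -0.10 over 17 genes (camera adjusted p = 0.226), and HLA-B, a DESeq2 call, had -0.98 (SE 0.25). That list passed, as lower, without Control replicate 1 (0.0164) or clone 2 (0.016). MHC class II genes had a median of -0.0077 and a mean of 0.38 over 4 genes, which camera ranked as lower (adjusted p = 0.686), with CIITA at 35.7 ± 4.71 CPM against 41.8 ± 3.19 CPM. Pattern recognition receptors and inflammasome genes had a median of 0.12 and a mean of -0.035 over 18 genes, which camera ranked as higher (adjusted p = 0.581), with PYCARD at 132 ± 3.79 CPM against 121 ± 6.02 CPM. Adhesion molecules and chemoattractant receptors had a median of 0.34 over 23 genes (adjusted p = 0.116) and passed without clone 1 (0.00156) or Control replicate 2 (0.0152). ITGB2, the beta chain of the leukocyte integrins, was at 771 ± 320.4 CPM against 542 ± 46.1 CPM, with 415 CPM in clone 1 and 859 and 1037 CPM in clones 2 and 3. In these 4 lists 0 genes passed in edgeR and 0 adjusted over the list alone. Coagulation and protease-activated receptor genes had a median of 0.051 over 10 genes, which camera ranked as lower (adjusted p = 0.974). In that list 0 genes passed in edgeR and 1 gene each way adjusted over the list alone, with ANXA2 at 179 ± 34.1 CPM against 160.1 ± 35.0 CPM. Of the receptors that serine proteases cleave, F2R had a log2 fold change of -1.56 (SE 0.40) and F2RL3 of 2.19 (SE 0.61).

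Genes of granules, lysosomes and protease control gave no list call in camera with all 6 libraries. Fry called 3 of these lists as changing in either direction: serine protease inhibitors (fry adjusted p = 0.00211), specific granule and calgranulin genes (0.0178) and granzymes (0.0366). The other azurophil granule genes had a median log2 fold change of 0.25 over 14 genes (camera adjusted p = 0.458), 0 edgeR calls and 1 lower adjusted over the list alone, and passed as higher without clone 1 (0.0397). SRGN, the granule proteoglycan serglycin, was at 1502 ± 435 CPM in ΔNSPs against 1301 ± 261 CPM in Control. Specific granule and calgranulin genes had a median of 0.28 and a mean of -0.065 over 6 genes, which camera ranked as higher (adjusted p = 0.473), with 2 higher adjusted over the list alone. MMP25 was at 210.4 ± 26.4 CPM against 150.2 ± 4.35 CPM. Serine protease inhibitors had a median of -0.17 over 12 genes (adjusted p = 0.581), with 1 higher and 2 lower adjusted over the list alone, and SERPINB1, an inhibitor of the targeted proteases, was at 349 ± 122 CPM against 313 ± 54.1 CPM. Granzymes and other serine proteases, not all of them granule proteins, had a median of -0.14 over 7 genes (adjusted p = 0.258). In that list 1 gene was lower adjusted over the list alone. HTRA2, which is not a granule protease, was at 73.7 ± 5.56 CPM against 73.0 ± 6.41 CPM. Cathepsins and lysosomal hydrolases had a median of -0.048 over 27 genes (adjusted p = 0.258), with 5 lower adjusted over the list alone. Its DESeq2 calls CTSB, ASAH1, PSAP and GAA had log2 fold changes of -0.97, -0.72, -0.72 and -0.60, and LAMP1 was at 479 ± 63.8 CPM against 382 ± 8.57 CPM. The lysosomal list passed as lower without Control replicate 1 (0.0164). In each of these 5 lists 0 genes passed in edgeR over all genes.

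Markers of maturation and of immature cells gave no list call in camera or fry with all 6 libraries. Monocyte and macrophage markers had a median of 0.41 over 15 genes (camera adjusted p = 0.433), 0 edgeR calls and 1 gene each way adjusted over the list alone. CD4 was at 244 ± 115 CPM in ΔNSPs against 275 ± 16.2 CPM in Control, and CEBPB, a DESeq2 call, had a log2 fold change of 1.12 (SE 0.31). Progenitor genes had a median of 0.20 over 19 genes (adjusted p = 0.0803), 0 edgeR calls and 0 adjusted over the list alone, and passed as higher without Control replicate 1 (0.0281). MYC was at 503 ± 128 CPM against 499 ± 54.4 CPM.

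Growth and housekeeping lists were also short of camera's threshold with all 6 libraries. As changing in either direction, fry called p53 targets (fry adjusted p = 0.00961), the unfolded protein response (0.0178) and BCL2 family and caspase genes (0.0425). DNA replication genes had a median of 0.17 over 23 genes (camera adjusted p = 0.0676) and passed as higher without Control replicate 1 (0.0173), Control replicate 2 (0.0212) or clone 2 (0.000416), with MCM7 at 771 ± 73.6 CPM in ΔNSPs against 743 ± 82.7 CPM in Control. Mitosis genes had a median of 0.096 over 26 genes (adjusted p = 0.258), with TPX2 at 707 ± 153 CPM against 709 ± 40.0 CPM. P53 target genes had a median of -0.16 over 22 genes (adjusted p = 0.647), with TNFRSF10B, a death receptor gene, at 57.9 ± 19.1 CPM against 80.6 ± 12.9 CPM. Unfolded protein response and ATF4 targets had a median of 0.11 over 23 genes (adjusted p = 0.423), with 2 genes each way adjusted over the list alone and CALR at 2092 ± 246 CPM against 2111 ± 27.0 CPM. BCL2 family and caspase genes had a median of 0.030 and a mean of -0.036 over 24 genes, which camera ranked as higher (adjusted p = 0.473), with MCL1 at 177 ± 15.9 CPM against 155 ± 5.93 CPM. NADPH oxidase and oxidative stress genes had a median of -0.069 over 19 genes (adjusted p = 0.686) and passed as lower without Control replicate 1 (0.0411), with CAT, the catalase gene, at 661 ± 5.18 CPM against 766 ± 143 CPM. In these lists 0 genes passed in edgeR, and 0 adjusted over the list alone outside the unfolded protein response.

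Oxidative phosphorylation genes of the nucleus had a median log2 fold change of -0.0017 over 32 genes, which camera ranked as higher (adjusted p = 0.974), with UQCRC1 at 423 ± 18.96 CPM in ΔNSPs against 419.9 ± 6.53 CPM in Control. Cytosolic ribosomal protein genes had a median of -0.074 over 53 genes (adjusted p = 0.258) and passed as lower without Control replicate 2 (0.000215) or clone 3 (0.0294), with RPL4 at 2518 ± 506 CPM against 2421 ± 297 CPM. As signs of RNA quality and selection, mitochondrially encoded mRNAs had a median of 0.10 over 13 genes (adjusted p = 0.581) and replication-dependent histones of 0.25 over 9 genes (adjusted p = 0.423). MT-CO1 was at 5537 ± 803 CPM against 5002 ± 1039 CPM, and HIST1H2BK at 10.96 ± 4.25 CPM against 10.6 ± 1.81 CPM. The mitochondrial list passed as higher without Control replicate 3 (0.012). Of markers of other cell types, lymphoid genes had a median of -0.32 over 7 genes (adjusted p = 0.458), with NKG7 at 154 ± 21.7 CPM against 217 ± 40.3 CPM. Erythroid and megakaryocyte genes had a median of 0.046 over 7 genes, which camera ranked as lower (adjusted p = 0.974), with HBB at 97.0 ± 15.1 CPM against 106 ± 29.8 CPM. Stromal, endothelial and epithelial genes had a median of -0.25 over 9 genes (adjusted p = 0.0676), with VIM, the vimentin gene, at 135 ± 87.3 CPM against 362 ± 140 CPM and 1 member lower adjusted over the list alone. That list passed as lower without Control replicate 1 (0.0173), clone 1 (0.0227) or clone 2 (0.00469), but not without clone 3 (0.799). Its mean log2 CPM, relative to the mean of all libraries, was -1.285 in clone 3 and 0.234 and 0.121 in clones 1 and 2. In Control replicates 1 to 3 it was 0.084, 0.461 and 0.385, so the low mean was that of clone 3 alone. In the other lists of this paragraph 0 genes passed adjusted over the list alone, and in none of them did a gene pass in edgeR over all genes.

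The clones differed from each other more than the Control lines did. The root mean square log2 difference between libraries of a group averaged 0.70 ± 0.049 over the 3 pairs of clones and 0.44 ± 0.076 over the 3 pairs of Control lines (mean ± SD). Pairs share libraries, so these SD are not over independent values. Clone 1 was at 0.744 and 0.709 from clones 2 and 3, and at 0.483 from each of Control replicates 2 and 3. Control replicate 1 was at 0.484 and 0.477 from those replicates. Clones 2 and 3 were at 0.647 from each other. The biological coefficient of variation fitted by edgeR was 25.2% in ΔNSPs and 13.6% in Control. With 3 libraries per group no exact test of this difference can go below p = 0.1. The labels call the depleted samples clones and the Control samples lines. An effect of deriving clones therefore cannot be told from one of the depletion, in this spread or in the changes of single genes. On the first principal component, which held 50% of the variance, clones 2 and 3 lay at 50.4 and 44.8, clone 1 at -20.0, Control replicate 1 at -4.40, and Control replicates 2 and 3 at -35.2 and -35.7. Clone 1 lay between the Control lines on this axis, and the second component (20.8%) separated clone 2 from clone 3.

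**Figure D3:**
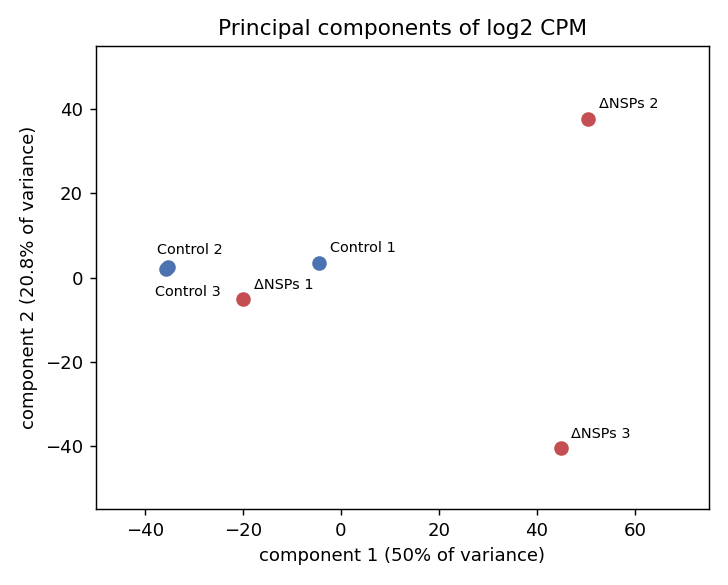
First and second principal components of log2 CPM over the tested genes, 1 point per library; blue points are Control lines and red points ΔNSPs clones. Clones 2 and 3 lie at 50.4 and 44.8 on the first component, and clone 1 lies at -20.0, between Control replicates 1 and 2.

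Whole chromosome regions differed in median expression in clones 2 and 3, by windows of 20 Mb over 10423 expressed genes, a comparison added after the data were seen. In clone 2 the 344 genes of chromosome 8 had a median log2 ratio of -0.61 to the Control mean, with 94.8% of them below 0, and the 391 genes of chromosome 15 had a median of 0.43. In clone 3 the window of chromosome 2 from 100000001 to 120000000 had a median of -0.60, that of chromosome 5 from 20000001 to 40000000 had 0.65, and the first window of chromosome 19, which holds ELANE, PRTN3 and TBXA2R, had 0.46. Clones 2 and 3 shared higher medians over chromosome 21 (0.35 and 0.41) and over chromosome 20 from 40000001 to 60000000 (0.56 and 0.57). They also shared lower medians over the window of chromosome X from 1 to 20000000 (-0.73 and -0.70). Control replicate 1 had a median of -0.42 in that window of chromosome X. It also had medians of 0.24 over chromosome 21 and of 0.20 and 0.24 in the windows of chromosome 1 from 220000001 and from 240000001. Clone 1 had a median of -0.19 over chromosome 13 and of -0.28 in its window from 20000001 to 40000000, with 84.6% of the genes below 0. These smaller values lay beyond every random gene set as well, but under the threshold of 0.3. Of the 146 windows, 23 were shifted by over 0.3, and beyond every one of 1000 random gene sets of the same size, in clone 2, 17 in clone 3 and 2 in Control replicate 1. In Control replicates 2 and 3 and in clone 1 the number was 0. Without the genes of these regions, TBXA2R among them, edgeR called 3 genes: CTSG and CCL2, and AC005726.4, an antisense gene named after its values were seen (adjusted p = 0.0773 over all genes and 0.0431 here). AC005726.4 overlaps ALDOC, and since the strand setting of the counting is not given, its counts are uncertain.

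**Figure D4:**
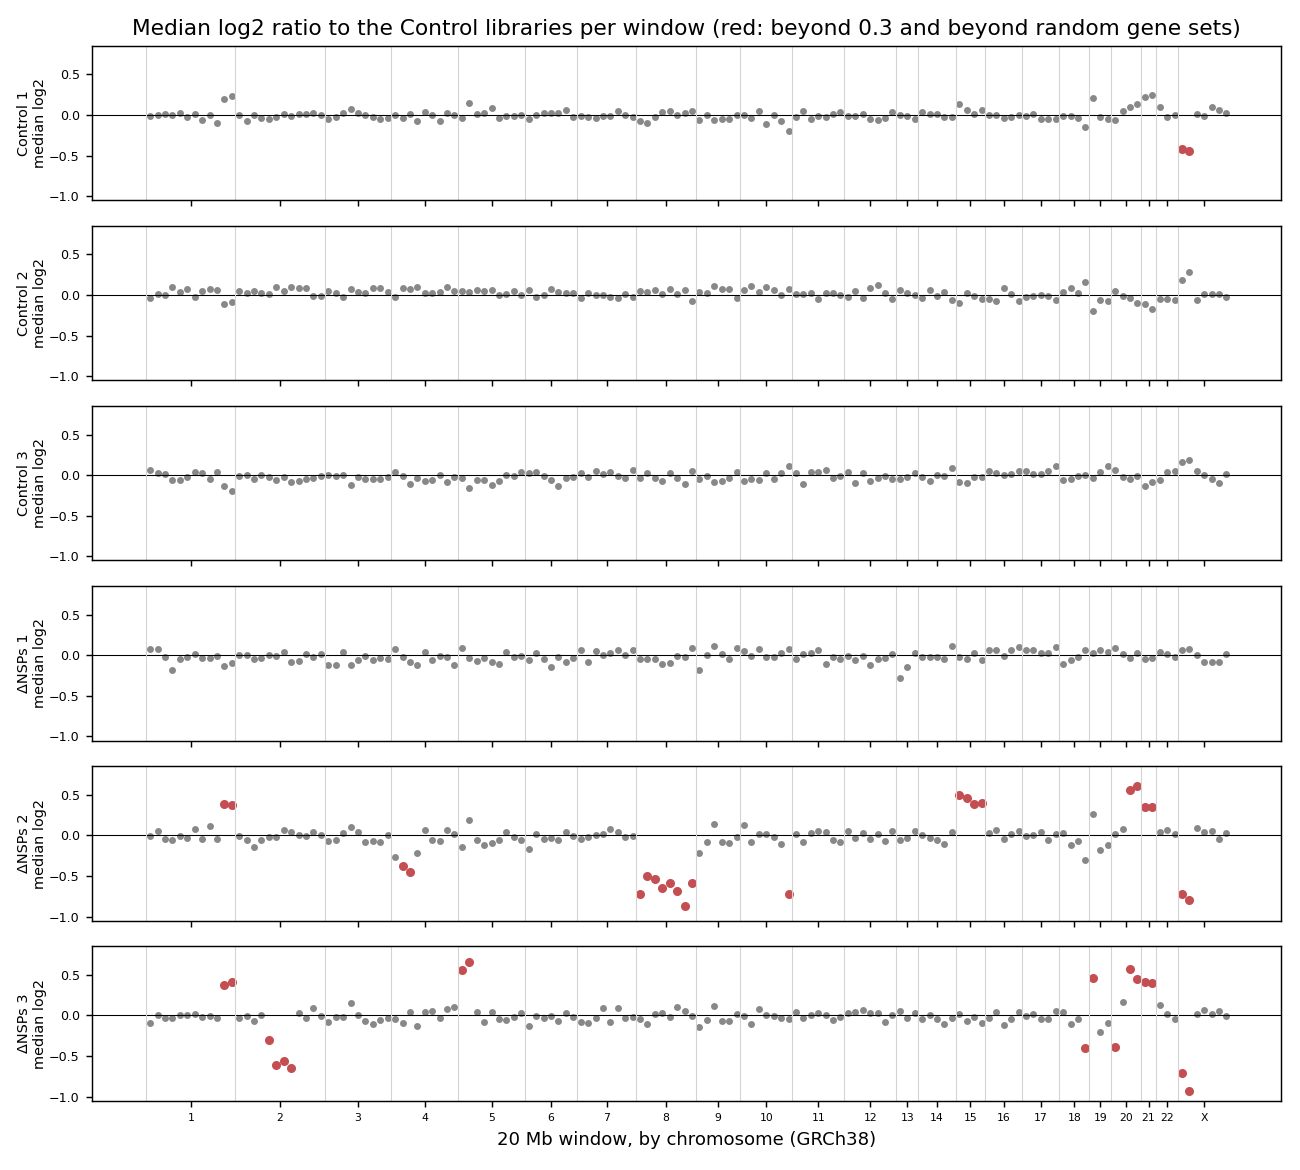
Median log2 ratio of expressed genes in windows of 20 Mb along each chromosome of GRCh38, 1 panel per library; a Control line is set against the mean of the other Control lines, a clone against the mean of all Control lines, and red points are windows beyond 0.3 and beyond random gene sets. Red windows appear in Control replicate 1 (2 windows), ΔNSPs clone 2 (23) and ΔNSPs clone 3 (17).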

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

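The settings chosen only after the data were seen were robust dispersions, voom without quality weights, leaving out shifted chromosome regions and the covariate for a shared background; all others were set earlier.

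CTSG, ELANE, PRTN3, CCL2 and TBXA2R kept their direction under every setting that tested them. The count of 3 changed genes (1 higher, 2 lower) was the same with DESeq2's size factors, the stricter filter and thinning, and was 4 without a filter. Without shifted regions the count was also 3, but 2 of these genes were shared: TBXA2R lies in a region left out, and AC005726.4 was called in addition to CTSG and CCL2. DESeq2 gave 515 genes (247 higher, 268 lower, 139 at least 2-fold). Limma voom with quality weights gave 2, 1 of them lower, and without weights 1, lower, and 0 higher. Robust dispersions gave 1, lower, and 0 higher, and the test against a 1.5-fold change gave 2, with 0 higher; unadjusted counts were 2628 for voom without weights, 2596 for robust dispersions and 376 against a 1.5-fold change. Leaving out 1 library gave 0 (without Control replicate 2 or 3, with 1408 and 1413 genes at an unadjusted p under 0.05) to 928 (without ΔNSPs clone 1), from 0 to 457 higher, 0 to 471 lower and 0 to 388 at least 2-fold. Control replicate 1 left out gave 20, clone 2 gave 2 and clone 3 gave 1. Each such fit has fewer samples. For the 928 genes without clone 1, a wrong label of that clone and the shifted chromosome windows were tested under other observations; for the other libraries no cause was tested.

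The values gave no sign that the replicate numbers pair the samples: correlations of deviations from the group mean between libraries of equal number were -0.432, -0.161 and -0.14. Those of Control replicate 1 with clones 2 and 3 were 0.263 and 0.217. Deviations within a group sum to 0, so the correlations depend on each other and cannot show that handling was unpaired. With the replicate number as a block, edgeR called 0 genes (0 higher, 0 lower, 0 at least 2-fold; 1779 at an unadjusted p under 0.05; DESeq2 without the block 515), and CTSG had a log2 fold change of -4.72 (adjusted p = 0.275). The block spends degrees of freedom on a pairing the values do not show. Under the block the list of NF-kB targets reversed (0.828), the stromal, endothelial and epithelial list passed (0.04), and MYC and HIST1H2BK reversed, at -0.013 and -0.0063.

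CTSG was past the threshold in most settings, with adjusted p from 3.33e-47 in DESeq2 to 0.275; with robust dispersions it was -4.61 (0.0858), and leaving out 1 library gave -4.94 to -4.27, with the call lost without Control replicate 2 (0.232), Control replicate 3 (0.217) or clone 2 (0.0932). ELANE passed in DESeq2 at -5.56 (4.36e-05; range over settings to 0.532), and leaving out 1 library gave -6.27 (without clone 1, 0.018) to -5.01 (without clone 2, 0.00159). PRTN3, with adjusted p from 0.00623 to 1 over the settings, ranged from -3.48 to -2.30 with 1 library left out, and passed without clone 1 (0.0391). With the share of the background of clones 2 and 3 as a covariate, PRTN3 was at -6.01 (0.0104). With clone 1 set to 0 and clones 2 and 3 to 100% it was at -6.14 (0.00623). These fits called 5 genes (1 higher, 4 lower, 5 at least 2-fold) and 11 genes (1 higher, 10 lower, 11 at least 2-fold), of which 1 and 5 had been used to estimate the share. A further version with shares set by hand was run first and is not tabulated. The covariate is linear on the log scale, so genes expressed in that background alone can be called by it.

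The lists past camera's threshold lost it with an estimated correlation: cholesterol 0.83, glycolysis and hypoxia 0.83, immediate early genes 0.443. Fry gave 0.645 for cholesterol and for glycolysis and hypoxia, and reversed oxidative phosphorylation (0.992). Without a filter, the erythroid list reversed (0.933). With 1 library left out, the lowest and highest adjusted p of the lists that changed side or direction were as follows. Glycolysis and hypoxia ran from 2.82e-05 to 0.124, NF-kB targets from 8.25e-05 (without Control replicate 1) to 0.937, and DNA replication from 0.000416 (without clone 2) to 0.396. Ribosomal proteins ran from 0.000215 (without Control replicate 2) to 0.938, adhesion molecules from 0.00156 (without clone 1) to 0.403, and stromal markers from 0.00469 (without clone 2) to 0.799. Mitochondrial mRNAs ran from 0.012 (without Control replicate 3) to 0.744, MHC class I from 0.016 (without clone 2) to 0.686, and the lysosomal list and the genes beside ELANE from 0.0164 (without Control replicate 1) to 0.686 and 0.799. Progenitor genes ran from 0.0281 (without Control replicate 1) to 0.219, azurophil genes from 0.0397 (without clone 1) to 0.891, and the NADPH oxidase list from 0.0411 (without Control replicate 1) to 0.985. The lists that stayed above the threshold but reversed in some were monocyte markers (0.124 to 0.891), MHC class II (0.218 to 0.964), pattern recognition (0.365 to 0.891), coagulation (0.574 to 0.985), oxidative phosphorylation (0.676 to 0.928) and erythroid markers (0.68 to 0.928).

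Among genes named by level, those near no change reversed. With voom and quality weights MYC was at -0.034, CALR at 0.015 and HIST1H2BK at -0.10; without weights MYC was at -0.014 and HIST1H2BK at -0.0060. Thinned, TPX2 was at 0.0011. With 1 library left out the log2 fold changes ran from -0.17 to 0.19 for MYC, -0.095 to 0.072 for CALR, -0.16 to 0.15 for TPX2 and -0.21 to 0.33 for HIST1H2BK. They ran from -0.039 to 0.42 for SERPINB1, -0.050 to 0.087 for HTRA2, -0.54 to 0.14 for CD4, -0.0043 to 0.30 for ANXA2 and -0.014 to 0.14 for MCM7. The others ran from -0.024 to 0.037 for UQCRC1, -0.11 to 0.17 for RPL4, -0.0078 to 0.29 for MT-CO1 and -0.33 to 0.067 for HBB. The causes were not tested.

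Over genes with at least 1 CPM in all 6 libraries, the within-group spread was 0.32 in Control and 0.47 in ΔNSPs. This set leaves out weakly expressed genes. It also leaves out genes expressed in some libraries and low in others, such as APP (182 and 196 CPM in clones 2 and 3, 0.215 CPM in clone 1). Which of these lowered the spread was not tested. Depth limits genes near the floor, such as TBXA2R in the clones and GZMH.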

Other observations

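In this part, the counts over other splits and the tests of a wrong label, of GC content, of few genes per window, of a single share of cells, of depleted cells in Control replicate 1 and of a mixture, in the form given, were chosen only after the result was seen, while the tests of calls inside shifted windows were set before their values were computed.

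A set of genes was expressed in ΔNSPs clones 2 and 3 and in Control replicate 1, and was low in the other libraries. APP, which encodes the amyloid precursor protein, was at 182 and 196 CPM in clones 2 and 3 and at 117 CPM in Control replicate 1, against 5.67 and 3.12 CPM in Control replicates 2 and 3 and 0.215 CPM in clone 1. CBR1, a carbonyl reductase gene, was at 37.1 and 36.1 CPM in clones 2 and 3, 19.3 CPM in Control replicate 1, 0.363 and 0.866 CPM in replicates 2 and 3, and 0 in clone 1. ERG, a transcription factor gene, was at 8.14 and 5.88 CPM in clones 2 and 3 and at 5.88 CPM in Control replicate 1, against 0.073 and 0.26 CPM in replicates 2 and 3. Other genes had the reverse pattern. CYB561 was at 13.4 and 17.1 CPM in Control replicates 2 and 3 and 24.3 CPM in clone 1, at 6.39 CPM in Control replicate 1 and at 0 in clones 2 and 3. SEMA6B was at 31.7 and 35.6 CPM in Control replicates 2 and 3, 24.7 CPM in clone 1 and 12.5 CPM in Control replicate 1, against 1.21 and 0.924 CPM in clones 2 and 3.

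The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real groups gave 3 changed genes, 1 higher and 2 lower, and the highest of the 9 other splits gave 59. For genes in a single direction and for those changed at least 2-fold, the highest other count was 47. Genes at an unadjusted p under 0.05 numbered 2638 for the real groups and 2423 at most in another split, DESeq2 calls numbered 515 and 719, and lists past the camera threshold numbered 3 and 18, with as many lists or more in 9 of the 10 splits, the real one included. The split of Control replicate 1 with ΔNSPs clones 2 and 3 against the rest gave the 59 genes and points to a structure of the samples other than the groups.

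Without ΔNSPs clone 1, edgeR called 928 genes in place of 3. A control library under a wrong label is argued against by PRTN3, at 0.277% of its Control mean in clone 1. The shifted chromosome windows held 30.5% of the 928 genes, with 645 outside, so they are not the whole source, although 18.2% of tested genes lay in them (odds ratio 2.09). Clone 1 lay on the same side of the Control mean as clones 2 and 3 for 74.6% of the 928 genes and beyond every Control line for 53.6%, with a median log2 difference of 0.20 in that direction against 0.88, but the same Control lines served for the call and for this comparison. Whether clone 1 shares the change in a weaker form, or differs from clones 2 and 3 in background, stays open.

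The shifted chromosome windows kept a median of 98.6% of their size, and 81.8% at the lowest, after removing trends with GC content, gene length and expression level, which argues against those as the cause. In each of the 42 shifts at least 75.4% of the genes lay on the side of the median. The windows were chosen by that median, which a few strongly changed genes hardly move, so this could not test such genes as the cause. Of the 42 shifts, 24 passed the threshold in 1 library alone, and gains and losses of chromosome regions in single clones may account for such shifts. Not all of the 24 were confined to that library. The first window of chromosome 19, shifted in clone 3, also had a higher median in clone 2, under the threshold of 0.3. The other 18 of the 42 shifts lie in 8 windows shifted alike in clones 2 and 3. Of these windows, the 2 on chromosome X were also shifted in Control replicate 1. A change in 1 clone alone does not account for these 18. Separate changes in each clone and a shared origin both stay open, since their origin was not tested. DNA copy number was not measured in these data.

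The genes called by the split of Control replicate 1 with clones 2 and 3 lay in the windows shifted alike in those clones for 28.8%, with 42 outside, so those windows are not the whole source. A single share of cells with all those shifts in Control replicate 1 is argued against: the share was 42.8% (95% interval 30.4% to 56.7%) on chromosome 1, 44.6% (33.6% to 59.1%) on chromosome 21 and 54.6% (47.9% to 64.4%) on chromosome X, which overlap, but 14.5% (8.22% to 19.8%) on chromosome 20, a gap of 28.1 percentage points at the widest. Cells of the clones with the depletion as the whole of Control replicate 1 are argued against by CTSG, ELANE and PRTN3, at 1897, 1085 and 539 CPM there, at least 8.57 times their highest level in a clone, and at 72.5%, 94.5% and 276% of the mean of Control replicates 2 and 3, so ELANE and PRTN3 also go against a part near 52.6% if the other cells were like those replicates, which was not measured, and a smaller part stays open. A candidate explanation is that Control replicate 1 mixed undepleted cells with the backgrounds of clone 1 and of clones 2 and 3. For 31 genes expressed in clones 2 and 3 and low in clone 1, its median was 52.6% of their level (quartiles 38.7% and 62.4%). For 11 genes of the reverse pattern, its median was 52.2% of the level of Control replicates 2 and 3 (quartiles 45% and 78%). The medians sum to 105% (95% bootstrap interval 91.9% to 136%), where 70% to 130% was required. The interval passes that upper bound. A single share did not hold for every gene: IGLL1 was at 365 CPM in Control replicate 1 against 254 and 116 CPM in clones 2 and 3. NCF1C was at 1.36 CPM there against 21.4 and 14.9 CPM. Of the 59 calls of the split, 24 were among the 31 genes and 0 among the 11. The targets were left out of both sets after a first result was seen. An intermediate state of all cells in this 1 library would give like values, which was not tested.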
